A study of Mus musculus with 14 samples.

How the data were processed

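RNA of aorta and liver was measured in 14 libraries of HuBL and BT3xHuBL mice, grouped by the tissue and genotype in the labels and numbered as in the sample titles. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy kit and libraries were made with Lexogen QuantSeq V2, a kit that reads transcripts near their 3′ ends, so a count stands for transcripts without a correction for gene length, and variable segments far from the 3′ end are thinly covered. The values deposited are counts per feature, not normalized. Per the submitters' processing notes, HTSeq 2.0 and the build GRCm38 were used; the aligner, the strand setting and the gene annotation are not given in the sources used here. The 2 tables, one per tissue, list the same 24732 features, and their header line is shifted against the first columns, which was allowed for by the sample titles at the head of the count columns. Feature starts in the tables were set against GENCODE M21 (GRCm38): of 23257 features found by name on the same chromosome, 1085 started within 1 kb, and the median offset was 192 kb. The tables' own coordinates are therefore not printed, and positions come from GENCODE M21 by gene symbol. Some feature names carry suffixes for overlapping or merged genes whose meaning is not given in the sources used here; 2094 tested aorta features and 1721 tested liver features carry the overlap mark, and reads shared with the overlapping gene could move them. The tables hold no mitochondrial genes.

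Depth was 41933263 to 65539765 counts per aorta library and 13228123 to 17992459 per liver library, and the 10 most abundant features took 7.3% to 8.6% and 17.7% to 21.0% of the counts. No library repeated another: chi-square per degree of freedom between libraries of a group was 12.7 to 80.7. Each tissue was fitted alone with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, robust quasi-likelihood fit and F-test of BT3xHuBL against HuBL, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM are counts scaled to a fixed library total, computed here from the deposited counts and TMM-scaled library sizes; intervals and floors on counts cover counting error only. Fold changes are edgeR's log2 values with a prior count of 0.125 and standard errors from the same fit. The interaction of genotype and tissue was fitted on all 14 libraries over genes kept in both tissues. Camera of limma 3.58.1 tested 47 lists of textbook markers and pathways, fixed before the data were examined as were the designs and most alternatives, where at least 5 members were tested. Its preset inter-gene correlation was 0.01, and an estimated correlation and fry, which tests whether a list's genes move in one direction on balance, were alternatives. List scores are mean log2 CPM per library with a prior count of 2, compared by exact permutation.

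Genes named in the text follow a rule set beforehand. Per tissue it takes up to 10 genes in each direction past the threshold with a mean of at least 1 CPM, filled by smallest p, and up to 4 genes of smallest p in lists called or close to the subject. It adds a short list of T cell, lipid and matrix genes, and the 10 interaction genes of smallest p. Predicted gene models are counted, not named, and some genes that the rule takes are not reported here. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, no low-count filter or a mean of at least 5 CPM, a fit without robust weights, a fit of both tissues, glmTreat against a fold of 1.5, the replicate number as a block, receptor genes left out, adipocyte and clock scores as covariates, and each library left out in turn. On counts simulated from the real means with 200 genes changed, edgeR recovered 43.3%, 62.7% and 86.4% of genes changed 1.5-, 2- and 3-fold in the aorta design (12 of 140 calls false) and 40.3%, 70.1% and 87.9% in the liver design (12 of 144 false). In the interaction it recovered 5.97%, 67.2% and 87.9% (14 of 121 false). DESeq2 made 43 false calls of 183 in the aorta design and 29 of 176 in the liver design. The adjustment is less strict when many genes pass, as with the 200 changed here. Far fewer passed in edgeR on the real data, so the recovered shares are too high for that setting. With no change simulated camera called 0 lists in either tissue, and with a single list changed 1.5-fold it called that list at both correlations. The simulated genes were drawn independently of each other, so these runs cannot show how the list test does on correlated genes. Exact permutations used SciPy 1.17.1 and plots matplotlib 3.10.9.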

Results

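RNA from the aorta and the liver of HuBL and BT3xHuBL mice was sequenced at 52 weeks on an ordinary chow diet. The labels do not spell out the strain names. In earlier work of this field, HuBL mice carry a human apolipoprotein B transgene, and BT lines carry a transgenic T cell receptor that recognises apolipoprotein B. The series title ties protective immunity and interleukin-10 to the stability of plaques. The comparison therefore addresses how the added T cell receptor goes with gene expression in the vessel wall and in the liver. There were 14 libraries in 4 groups: 3 HuBL aortas, 3 BT3xHuBL aortas, 4 HuBL livers and 4 BT3xHuBL livers. Aorta libraries held 41933263 to 65539765 counts and liver libraries 13228123 to 17992459, over 24732 features. Nothing in the labels says whether libraries came from separate animals, so p-values measure the spread among these libraries, which may be technical.

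In the aorta, BT3xHuBL mice had more transcript of a circadian output gene and less of kappa antibody light chain segments. Dbp, a transcription factor that carries the output of the circadian clock, rose from 32.4 ± 0.235 CPM in HuBL to 88.0 ± 17.3 CPM in BT3xHuBL (SD, n = 3 each), a log2 fold change of 1.44 (SE 0.13). Tcap, the titin-cap protein of the muscle Z-disc, rose from 18.0 ± 1.5 to 41.9 ± 6.86 CPM, a log2 fold change of 1.22 (SE 0.13). Igkv10-96 and Igkv8-30, variable segments of the kappa antibody light chain used by B lineage cells, fell from 13.1 ± 2.33 to 4.02 ± 0.512 CPM and from 3.83 ± 0.462 to 0.486 ± 0.214 CPM. Their log2 fold changes were −1.71 (SE 0.18) and −2.98 (SE 0.36). These were the 4 genes of 15400 tested that passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p = 0.0089 for Dbp, Tcap and Igkv10-96 and 0.0247 for Igkv8-30. For each of them, every BT3xHuBL library lay on the same side of every HuBL library. Over all tested genes such separation held for 1428 (9.3%), where chance gives 10%.

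In GENCODE M21 (GRCm38), Dbp lies on chromosome 7 from 45705088 to 45710203 and Tcap on chromosome 11 from 98383811 to 98384953, both protein-coding. Igkv10-96 lies on chromosome 6 from 68631963 to 68632442 and Igkv8-30 on the same chromosome from 70117061 to 70117620. Dbp was counted under a feature name that marks an overlapping gene, and light chain segments share near-identical sequence, so their levels are uncertain to that degree. The same mark is on Glul, Plin4, Foxp3, Il10ra, Il1a, Cd74, Lck, Alg10b and Ptp4a1. The count of called aorta genes was 75 with DESeq2 (32 higher, 43 lower), 0 with limma-voom and 0 with the adipocyte score as a covariate, and 629 genes had an unadjusted p under 0.05 where chance gives 770. It was 2 without HuBL replicate 1, 0 without HuBL replicate 2 or replicate 3, and 27 without BT3xHuBL replicate 3, whose genotype label the receptor counts do not settle.

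**Figure D1:**
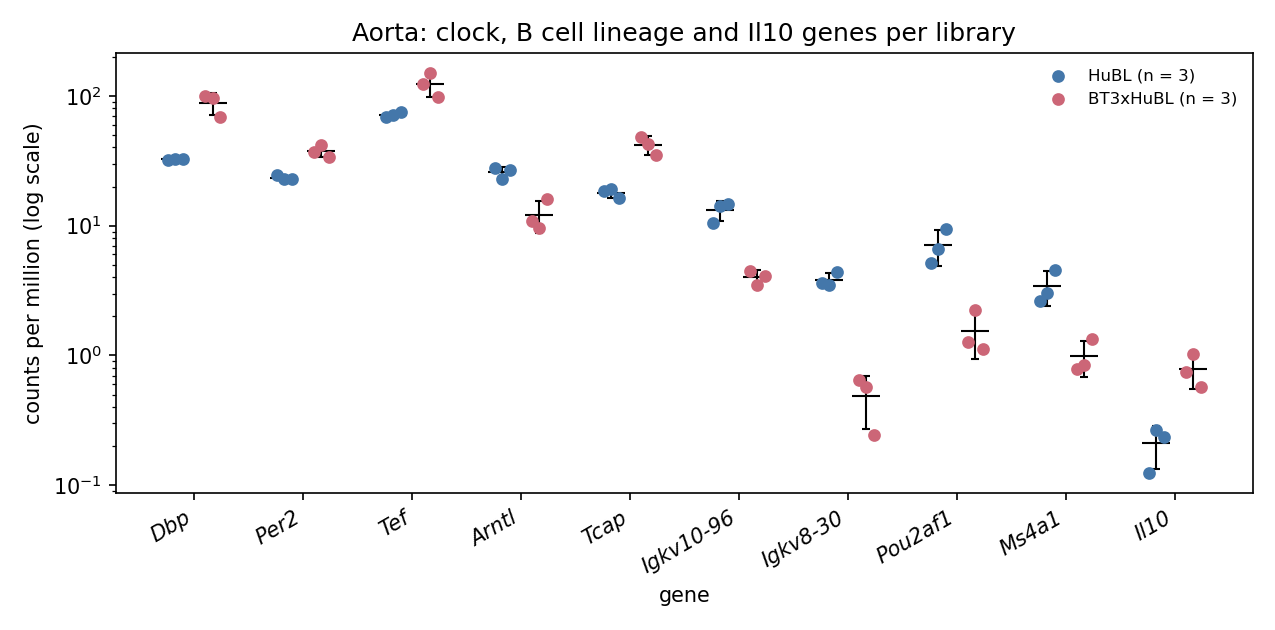
Library-scaled counts (CPM, log scale) of 10 genes in each aorta library; blue points are HuBL and red points BT3xHuBL, and black bars give the mean and SD of 3 libraries. Dbp lay at 68.2 to 99.0 CPM in the BT3xHuBL libraries and at 32.2 to 32.7 CPM in the HuBL libraries, and Igkv8-30 was at most 0.646 CPM in BT3xHuBL and at least 3.52 CPM in HuBL.

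No other aorta gene passed. Among those of smallest p, values above those of HuBL were measured for Per2, a repressor of the core clock (log2 fold change 0.69, SE 0.10), for Tef, a relative of Dbp (0.79, SE 0.14), for Myocd, the coactivator of smooth muscle genes (1.06, SE 0.15), and for Actn2, a sarcomeric actinin (1.48, SE 0.23). The heart and skeletal muscle list was not called, with 6 of 11 genes above 0 and a median of 0.16 (camera adjusted p = 0.55). In the aorta its median was below 0 without HuBL replicate 1 (−0.019), HuBL replicate 3 (−0.012) or BT3xHuBL replicate 1 (−0.11). Chil3, a chitinase-like protein of macrophages, gave 1.55 (SE 0.29), and Tent5b, Cys1 and Rasl10b gave 0.82, 0.70 and 0.80. edgeR's adjusted p for these genes lay between 0.0875 and 0.339. Values below those of HuBL were measured for Pou2af1, a coactivator of antibody genes (−2.19, SE 0.31), Ms4a1, which encodes the B cell antigen CD20 (−1.79, SE 0.32), and Arntl, the activator of the core clock (−1.08, SE 0.18). Ly6c2, a marker of inflammatory monocytes, gave −1.48 (SE 0.26), Cemip, which degrades hyaluronan, −1.13 (SE 0.18), and Leo1, Btg2 and Rasl11a −0.51, −0.63 and −0.57. Their adjusted p in edgeR lay between 0.0881 and 0.413.

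Gene lists fixed beforehand were then compared with all other genes by camera. Of 43 lists in the aorta, 14 were called at a preset correlation of 0.01, 6 higher and 8 lower in BT3xHuBL. With an estimated correlation camera called 0 (6 at an unadjusted p under 0.05), and fry also called 0 (5 unadjusted). Fry's mixed test, which asks whether genes of a list change in either direction and compares them with no other genes, passed 5 lists, 3 of them called by camera, with a smallest adjusted p of 0.0455. An exact two-sided permutation of the list scores cannot go below p = 0.1 with 3 libraries against 3, and 0.1 was the smallest found.

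The circadian clock list stood out: 12 of its 15 genes lay above 0 and 3 below, with a median log2 fold change of 0.65. Of these genes, 1 passed over all genes tested (Dbp) and 11 passed when adjusted over the list alone. Camera gave the list adjusted p = 1.98e-17, and adjusted p = 0.18 with an estimated correlation.

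Antibody and B cell genes lay lower in BT3xHuBL aortas. In the plasma cell and immunoglobulin list, 15 of 16 genes were below 0 with a median of −1.47, and their summed level was 1750 CPM in HuBL and 503 CPM in BT3xHuBL. None passed over all genes, and 6 did when adjusted over the list alone. Igkc, the constant part of the kappa light chain, measured 449 ± 153 and 97.1 ± 55.8 CPM in HuBL and BT3xHuBL (SD, n = 3 each). Jchain, which joins secreted antibodies, gave a log2 fold change of −1.65 (SE 0.43), and Mzb1, a chaperone of antibody secretion, −1.68 (SE 0.47). Camera gave adjusted p = 5.01e-19, and adjusted p = 0.18 with an estimated correlation. In the B cell list, 13 of 14 genes were below 0 with a median of −0.61, 0 passed over all genes and 3 passed when adjusted over the list alone. Cd79a and Cd79b, the signalling chains of the B cell receptor, gave −1.32 (SE 0.33) and −0.64 (SE 0.20). In camera this list had adjusted p = 1.29e-09, and adjusted p = 0.283 with an estimated correlation. Among variable segments, 56 of 63 kappa and 54 of 65 heavy chain segments were below 0, with medians of −1.72 and −1.36, and of 3 lambda segments 1 was below 0, with a median of 0.14.

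The medians of the interferon lists had opposite signs in the aorta, and the difference between the lists was not tested. All 18 genes of the type I interferon list were below 0 with a median of −0.29, and 3 passed when adjusted over the list alone, 0 over all genes. Isg15, a ubiquitin-like antiviral protein, gave −0.68 (SE 0.19) and Irf7, the inducer of type I interferon, −0.50 (SE 0.14). The camera test gave adjusted p = 1.63e-11, and adjusted p = 0.368 with an estimated correlation. The median was −0.13 without BT3xHuBL replicate 2. In the interferon gamma list, 14 of 17 genes were above 0 with a median of 0.22, and 1 passed when adjusted over the list alone. Gbp4, a guanylate-binding protein of cell defence, measured 9.58 ± 0.766 and 23.1 ± 7.56 CPM in HuBL and BT3xHuBL, and Igtp, an immunity-related GTPase, gave a log2 fold change of 0.65 (SE 0.18), or 0.42 without BT3xHuBL replicate 1. For this list camera's adjusted p was 3.33e-08, and adjusted p = 0.497 with an estimated correlation. Its median was 0.02 without BT3xHuBL replicate 1 and 0.37 without HuBL replicate 3 or BT3xHuBL replicate 3.

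Matrix and proliferation genes were slightly lower. All 19 genes of the collagen, elastin and matrix list were below 0 with a median of −0.16, and none passed over all genes or when adjusted over the list alone. Eln, the elastin gene, measured 5436 ± 499 and 3645 ± 1343 CPM in HuBL and BT3xHuBL, and Lox, which crosslinks elastin and collagen, and Fbn1, a microfibril protein, gave log2 fold changes of −0.31 (SE 0.10) and −0.20 (SE 0.09). Col1a1 and Col3a1, the main fibrillar collagens of the wall, gave −0.20 (SE 0.15) and −0.16 (SE 0.13). Without BT3xHuBL replicate 2 Eln, Col1a1 and Col3a1 were at −0.37, −0.087 and −0.041, and without BT3xHuBL replicate 3 Eln and Col1a1 were at −0.91 and −0.33. Col1a1 was at −0.32 without HuBL replicate 2, and without HuBL replicate 3 the collagens were at −0.088 and −0.105. For these matrix genes camera gave adjusted p = 1.17e-06, and adjusted p = 0.497 with an estimated correlation. The median was −0.08 without BT3xHuBL replicate 2, −0.10 without HuBL replicate 3 and −0.26 without BT3xHuBL replicate 3. The stellate cell and fibrosis list, which shares collagen genes with it, had 10 of 11 genes below 0 and a median of −0.16, 0 genes passing when adjusted over the list alone, and adjusted p = 0.0216 in camera, with adjusted p = 0.497 with an estimated correlation. That call was lost without BT3xHuBL replicate 2 (adjusted p = 0.345). In the cell cycle list, 17 of 17 genes were below 0 with a median of −0.15, and 1 passed when adjusted over the list alone. Top2a, a topoisomerase of dividing cells, gave −0.37 (SE 0.09) and Rrm2, a subunit of ribonucleotide reductase, −0.35 (SE 0.13). By camera the cycle genes had adjusted p = 0.000765, and adjusted p = 0.283 with an estimated correlation. The median was −0.10 without BT3xHuBL replicate 1.

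Immediate early genes also lay lower in the aorta, with 10 of 13 below 0 and a median of −0.15. Egr1 and Jun, transcription factors induced within minutes of stimulation, gave −0.52 (SE 0.15) and −0.47 (SE 0.17), and 1 gene passed when adjusted over the list alone. The early genes had adjusted p = 9.22e-05 in camera, and adjusted p = 0.283 with an estimated correlation. The median was −0.09 without HuBL replicate 2 and −0.06 without BT3xHuBL replicate 1. Of 16 matrix proteases, 11 were below 0 with a median of −0.08, and 1 passed when adjusted over the list alone. The aggrecan-cleaving proteases Adamts4 and Adamts1 gave −0.65 (SE 0.23), or −0.43 without BT3xHuBL replicate 2, and 0.38 (SE 0.11). The proteases had adjusted p = 0.0451 in camera, and adjusted p = 0.497 with an estimated correlation. Without HuBL replicate 2, BT3xHuBL replicate 1 or BT3xHuBL replicate 3 it was 0.434, 0.134 or 0.335.

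In the aorta, adipocyte genes lay higher in BT3xHuBL as a list. All 12 adipocyte genes were above 0 in BT3xHuBL with a median of 0.31, and their summed level was 1150 CPM in HuBL and 1410 CPM in BT3xHuBL. Pnpla2, the first lipase of stored fat, gave 0.35 (SE 0.10), Pparg, the regulator of fat cell formation, 0.30 (SE 0.10), and Plin4, a lipid droplet coat protein, 0.22 (SE 0.09), or 0.14 without BT3xHuBL replicate 1. Adipocyte genes had adjusted p = 1.74e-07 in camera, and adjusted p = 0.497 with an estimated correlation. None of the 12 passed over all genes and 1 did when adjusted over the list alone, and the median was 0.20 without HuBL replicate 3 and 0.20 without BT3xHuBL replicate 1. In the brown adipocyte list 7 of 11 genes were below 0 with a median of −0.18 (camera adjusted p = 0.6); it was called higher without BT3xHuBL replicate 2 (0.0167) and lower without BT3xHuBL replicate 3 (0.00126). With the adipocyte score as a covariate, Dbp gave 1.39 (SE 0.18) and Tcap 1.04 (SE 0.15), with edgeR adjusted p = 0.409 for both. The pericentral hepatocyte list was called higher, on 5 measured genes with a median of 0.36, 3 of which passed when adjusted over the list alone. Glul, which makes glutamine and carries the overlap mark in its feature name, gave 0.36 (SE 0.11) and Cyp2e1, an oxidising enzyme, 1.17 (SE 0.31). Both are also expressed outside the liver. This list had adjusted p = 4.06e-05 in camera, and adjusted p = 0.18 with an estimated correlation. Smaller medians were found for the liver sinusoidal endothelium list (0.17), which holds the water channel Aqp1 (0.24, SE 0.08), and the xenobiotic list (0.15). Camera's adjusted p was 0.00676 and 0.0219 for these lists, and adjusted p = 0.497 with an estimated correlation for both. The call of the former was lost without HuBL replicate 1 (adjusted p = 0.0606) or BT3xHuBL replicate 1 (0.134), and that of the latter without HuBL replicate 3 (0.37) or BT3xHuBL replicate 3 (0.146).

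The genes closest to the study's subject did not pass in the aorta. Il10, which encodes interleukin-10, had 8, 11 and 15 counts in the HuBL libraries and 43, 69 and 35 in the BT3xHuBL libraries, or 0.210 ± 0.0761 and 0.784 ± 0.234 CPM. Its log2 fold change was 1.91 (SE 0.55), with an adjusted p of 0.899 in edgeR, and the genotypes did not overlap. Il10 lies on chromosome 1 from 131019845 to 131024974 in GENCODE M21 (GRCm38). Maf, a transcription factor that drives Il10 in T cells, gave 0.25 (SE 0.10), Il10ra, the interleukin-10 receptor, −0.10 (SE 0.07), or −0.060 without HuBL replicate 3, and Foxp3, the factor of regulatory T cells, −0.55 (SE 0.95). The regulatory T cell and IL-10 list had a median of −0.12 and the IL-10 response list −0.05, with camera adjusted p = 0.6 and 0.55. The T cell list had a median of −0.04 and the type 1 T cell and cytotoxic list 0.05, each with camera adjusted p = 0.6. The T cell receptor constant genes Trac, Trbc1 and Trbc2 gave 0.65 (SE 0.35), 0.32 (SE 0.54) and 0.18 (SE 0.41), Cd4 0.01 (SE 0.23), and Gzma, a granzyme of killer cells, 1.47 (SE 0.58). With 1 library left out in turn, Foxp3 ran from −1.12 to 0.24, Trbc1 from 0.042 to 0.75, Trbc2 from −0.085 to 0.51 and Cd4 from −0.33 to 0.18. The follicular helper and germinal centre list had a median of −0.08 (camera adjusted p = 0.649).

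Macrophage and smooth muscle lists were not called in the aorta with all libraries. Spp1 and Gpnmb, products of lipid-laden macrophages, measured 14454 and 5314 CPM in HuBL and 11584 and 4479 CPM in BT3xHuBL. Their log2 fold changes were −0.32 and −0.25, or −0.17 for Spp1 without HuBL replicate 2 and −0.16 for Gpnmb without BT3xHuBL replicate 1. Their list had a median of −0.08 and camera adjusted p = 0.0517; in the aorta it was called lower with no filter (0.0469), without HuBL replicate 3 (0.0051) and without BT3xHuBL replicate 2 (8.28e-05). The resident macrophage list gave 0.09 (camera adjusted p = 0.32), with the complement gene C1qa at 0.15 (SE 0.11), or 0.080 without HuBL replicate 1 and 0.28 without HuBL replicate 2, and the inflammatory myeloid list −0.00054, with a mean of 0.08 (camera adjusted p = 0.983). The general macrophage marker Cd68 gave −0.05 (SE 0.10), and −0.11 to 0.042 with 1 library left out. The smooth muscle contractile list gave 0.01 (camera adjusted p = 0.132), with Acta2, smooth muscle actin, at −0.10 (SE 0.15) and at −0.26 to 0.017 with 1 library left out. The contractile list was called higher without HuBL replicate 1 (0.00186) or BT3xHuBL replicate 2 (8.96e-05). Without BT3xHuBL replicate 3 the resident macrophage list was called higher (0.0356), as was the inflammatory myeloid list without HuBL replicate 2 (0.0199). The cholesterol synthesis list gave −0.06 (camera adjusted p = 0.32). Apob, the mouse apolipoprotein B gene, gave 0.16 (SE 0.09), or 0.093 without HuBL replicate 3. The sterol export and LXR, lipoprotein and clearance, and bile acid lists gave 0.02, −0.00206 and −0.02, with camera adjusted p = 0.257, 0.649 and 0.729; for the latter pair the test pointed up, against the sign of the median. Over the 29 lists not called, camera's adjusted p ran from 0.0517 to 0.983.

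In the liver, the lists of interferon-induced genes and of T cell genes lay lower in BT3xHuBL, and that of fat oxidation higher, but no single gene passed. Each of these list calls was lost in camera with an estimated correlation, with adjusted p = 0.278 with an estimated correlation for both interferon lists and adjusted p = 0.319 for the T cell and fat oxidation lists. Of 12453 genes tested with edgeR, 0 passed, with a smallest adjusted p of 0.131. DESeq2 called 130 (34 higher, 96 lower) and limma-voom 0. At an unadjusted p under 0.05 there were 1381 genes (711 higher, 670 lower), where chance gives 623. The genotypes did not overlap for 818 genes (6.6%), where chance gives 2.86%. The count of called genes was 5 without BT3xHuBL replicate 2, 2 without BT3xHuBL replicate 3, 5 in the fit of both tissues and 52 with the clock score as a covariate.

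Of the liver genes above HuBL with the smallest p, Ugt1a1, which conjugates bilirubin, measured 106 ± 7.07 CPM in HuBL and 158 ± 7.77 CPM in BT3xHuBL (SD, n = 4 each). Fmo2, a flavin monooxygenase, gave a log2 fold change of 1.74 (SE 0.27), Steap2, a metalloreductase, 1.86 (SE 0.30), and Psat1, an enzyme of serine synthesis, 3.38 (SE 0.65). Mmp14, a membrane-bound collagenase, gave 0.59 (SE 0.12), and Tmtc2, Rab11fip4, Alg10b, Eif4ebp2 and Sema6d lay between 0.58 and 1.57. edgeR's adjusted p for these 10 genes lay between 0.131 and 0.214. Lower values came from Apela, a peptide hormone gene listed under an older symbol, at 6.45 ± 3.20 and 0.428 ± 0.294 CPM in HuBL and BT3xHuBL. Several of the others are induced by interferon: Bst2, which tethers viruses (−0.58, SE 0.10), Ubd, a ubiquitin-like protein (−1.43, SE 0.24), H2-D1, a class I antigen-presenting molecule (−0.65, SE 0.11), and Apol9b (−0.64, SE 0.11). The T cell chemokine Ccl5 gave −1.24 (SE 0.20), Tat, which degrades tyrosine, −0.86 (SE 0.14), and Slc25a51, the mitochondrial NAD carrier, −0.55 (SE 0.09). Igfbp3 and Serpina5 gave −0.53 (SE 0.10) and −2.20 (SE 0.40). Their adjusted p in edgeR lay between 0.131 and 0.165. In GENCODE M21 (GRCm38), Ugt1a1 lies on chromosome 1 from 88211959 to 88218997, Apela on chromosome 8 from 65028417 to 65037336 and H2-D1 on chromosome 17 from 35262730 to 35267499, and Ugt1a1 and H2-D1 carry the overlap mark in their feature names.

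Of 39 lists in the liver, camera called 17 at the preset correlation, 4 higher and 13 lower in BT3xHuBL. With an estimated correlation it called 0 (5 at an unadjusted p under 0.05), and fry called 0 (8 unadjusted). Its mixed test passed 10 lists, 8 of them called by camera, with a smallest adjusted p of 0.00302. An exact two-sided permutation of list scores gave p = 0.0286, the smallest that 4 libraries against 4 can give, for 4 lists: interferon gamma, T cell, periportal hepatocyte, and regulatory T cell and IL-10. These p-values were not adjusted over the 39 lists.

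All 17 genes of the interferon gamma list were below 0 with a median of −0.60, and 12 passed when adjusted over the list alone, 0 over all genes. Psmb8 and Psmb9, subunits of the immunoproteasome, gave −0.46 (SE 0.09) and −0.60 (SE 0.12), Irf1, the first regulator of the response, −0.38 (SE 0.08), and the chemokine Cxcl10 −1.41 (SE 0.28). All 18 genes of the type I interferon list were below 0 with a median of −0.90, 4 of them passing when adjusted over the list alone. Xaf1, an antiviral apoptosis factor, gave −0.84 (SE 0.22), and Irf7 measured 410 ± 29.2 and 253 ± 90.5 CPM in HuBL and BT3xHuBL. Camera's adjusted p was 1.78e-18 and 3.2e-17 for these lists, and adjusted p = 0.278 with an estimated correlation for both. DESeq2 called 7 genes of the former and 3 of the latter, all lower.

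T cell genes were below 0 for 18 of 18 members with a median of −0.70, and 7 passed when adjusted over the list alone, 0 over all genes. Bcl11b, a factor of T cell identity, measured 1.21 ± 0.343 and 0.439 ± 0.0218 CPM in HuBL and BT3xHuBL. Cd4 gave −1.34 (SE 0.36), Lck, the kinase of T cell receptor signalling, −0.96 (SE 0.31), Trbc2 −1.02 (SE 0.26), Trbc1 −0.18 (SE 0.34) and Trac −0.50 (SE 0.39). With 1 library left out, Trac ran from −0.77 (without BT3xHuBL replicate 2) to −0.19 and Trbc1 from −0.40 (without HuBL replicate 2) to 0.078, both highest without HuBL replicate 3. T cell genes had adjusted p = 4.45e-10 in camera, and adjusted p = 0.319 with an estimated correlation. In the type 1 T cell and cytotoxic list 8 of 8 genes were below 0 with a median of −0.63, with Gzmb, a granzyme, at −1.07 (SE 0.34). Camera gave it adjusted p = 7.42e-05, and adjusted p = 0.319 with an estimated correlation. In the regulatory T cell and IL-10 list, 5 of 8 genes were below 0 with a median of −0.46. Lag3, an inhibitory receptor, gave −0.96 (SE 0.20), Ikzf2, the factor Helios, −0.90 (SE 0.30), and Il10ra, outside the list, −0.47 (SE 0.19). Camera's adjusted p for that list was 0.0159, and adjusted p = 0.278 with an estimated correlation. It was 0.0576 without HuBL replicate 4 and 0.0523 without BT3xHuBL replicate 3. Il10 was at 1 to 8 counts per liver library and was not tested.

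**Figure D2:**
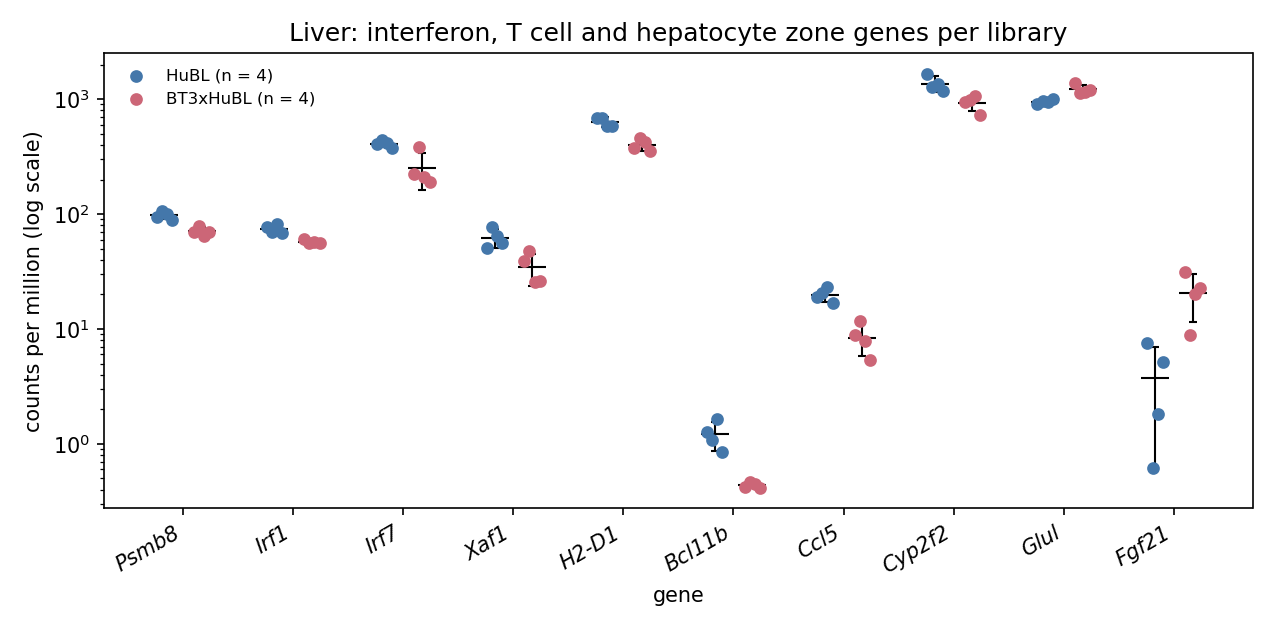
Library-scaled counts (CPM, log scale) of 10 genes in each liver library; blue points are HuBL and red points BT3xHuBL, and black bars give the mean and SD of 4 libraries. Bcl11b was at most 0.463 CPM in BT3xHuBL and at least 0.844 CPM in HuBL, and Ccl5 lay at 5.35 to 11.6 CPM in BT3xHuBL and 16.9 to 23.0 CPM in HuBL; no gene shown passed the test over all genes.

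The lists of hepatocyte zones had medians of opposite sign, and the difference between them was not tested. Of 10 periportal genes, 9 were below 0 with a median of −0.44, and 2 passed when adjusted over the list alone. Cyp2f2, a cytochrome of the portal zone, measured 1368 ± 214 and 930 ± 142 CPM in HuBL and BT3xHuBL, and Aldh1b1, an aldehyde dehydrogenase, gave −0.82 (SE 0.21). Of 10 pericentral genes, 8 were above 0 with a median of 0.25, and 2 passed when adjusted over the list alone. Glul, which marks hepatocytes around the central vein, measured 955 ± 35.7 and 1216 ± 113 CPM, and Axin2, a target of Wnt signalling, gave 0.40 (SE 0.16). Camera's adjusted p was 1.42e-05 and 0.0159 for the portal and central lists, and adjusted p = 0.278 with an estimated correlation for both. The portal median was −0.27 without BT3xHuBL replicate 1. The central list's adjusted p was 0.0918 without HuBL replicate 4. Fat oxidation and PPAR alpha genes were above 0 for 13 of 17 with a median of 0.21, and 0 passed over all genes or when adjusted over the list alone. Fgf21, a fasting hormone of the liver, measured 3.76 ± 3.14 and 20.7 ± 9.22 CPM, and Cyp4a14, a fatty acid hydroxylase, 74.9 ± 68.0 and 550 ± 488 CPM. Fat oxidation genes had adjusted p = 0.000569 in camera, and adjusted p = 0.319 with an estimated correlation.

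Matrix genes lay higher in the liver, with 18 of 18 above 0 and a median of 0.33. Lum, a collagen-binding proteoglycan, gave 1.04 (SE 0.42), Fn1, fibronectin, 0.41 (SE 0.19), and Col1a1 and Col3a1 0.67 (SE 0.52) and 0.52 (SE 0.36). Without BT3xHuBL replicate 1 the 2 collagens gave 0.28 and 0.26, Col1a1 gave 1.03 without HuBL replicate 3 and 0.44 without HuBL replicate 1, and without BT3xHuBL replicate 4 Fn1 gave 0.21. Liver matrix genes had adjusted p = 0.00108 in camera, and adjusted p = 0.657 with an estimated correlation. It was 0.0681 without BT3xHuBL replicate 1. Markers of bile duct cells were above 0 for 7 of 8, with a median of 0.66 and with Epcam at 0.89 (SE 0.39) and Krt19 at 0.95 (SE 0.43), or 0.39 and 0.46 without BT3xHuBL replicate 1. Bile duct genes had adjusted p = 0.0481 in camera, and adjusted p = 0.657 with an estimated correlation. It was lost without HuBL replicate 2 (0.206), HuBL replicate 3 (0.182), BT3xHuBL replicate 1 (0.339) or BT3xHuBL replicate 3 (0.125). Lower lists included heat shock (10 of 10 below 0, median −0.38), with the chaperones Hspe1 and Hspb1 at −0.49 (SE 0.13) and −0.75 (SE 0.24), inflammatory myeloid (9 of 12, −0.43), with the cytokines Il1a and Ccl2 at −0.57 (SE 0.18) and −0.79 (SE 0.27), and male-biased liver (8 of 10, −0.46), with Cyp4a12a and Cyp2d9 at −0.63 (SE 0.23) and −0.51 (SE 0.26). Camera's adjusted p was 0.00075, 0.0016 and 0.00313 for these lists, and adjusted p = 0.657, 0.524 and 0.657 with an estimated correlation. The heat shock call was lost without HuBL replicate 3 (adjusted p = 0.0761, median −0.09), and its median was −0.66 without BT3xHuBL replicate 3. Without BT3xHuBL replicate 4 the myeloid and male-biased medians were −0.20 and −0.28, and without BT3xHuBL replicate 3 the latter was −0.98. Cyp2d9 was at −0.30 without BT3xHuBL replicate 4. The sex of the mice is not given in the sources used here. In the female-biased liver list, with 3 measured genes too small for camera, 3 of 3 were above 0 with a median of 2.04 and a summed level of 7.91 CPM in HuBL and 37.0 CPM in BT3xHuBL (exact two-sided permutation p of the score = 0.314). Its scores were 3.25 and 4.81 in BT3xHuBL replicates 1 and 4, 0.951 and 0.174 in replicates 2 and 3, and 0.16 to 2.11 in HuBL. The 4 measured genes of the sex chromosome list had a median of 0.031. Their score lay between 5.52 and 5.76 in every liver library, so this score set no library apart.

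Other immune lists were called lower with smaller medians. The B cell, plasma cell and immunoglobulin, and MHC class II lists had 10 of 11, 9 of 13 and 8 of 8 genes below 0, with medians of −0.34, −0.35 and −0.23 and camera adjusted p = 0.0258, 0.0423 and 0.0371, each with adjusted p = 0.657 with an estimated correlation. Ighm, the first antibody heavy chain, measured 45.0 ± 27.0 and 12.3 ± 2.96 CPM in HuBL and BT3xHuBL, Igkc gave −0.53 (SE 0.23), the heavy chain gene Ighg2b lay above HuBL at 0.93 (SE 0.37), and the class II genes H2-Ab1 and Cd74 gave −0.33 (SE 0.24) and −0.24 (SE 0.20). The class II genes were at −0.62 and −0.43 without BT3xHuBL replicate 1, and at −0.21 and −0.074 without HuBL replicate 3, where Igkc was at −0.28. In the cell cycle list 12 of 15 genes were below 0 with a median of −0.30, with Birc5, a survival factor of dividing cells, at −0.54 (SE 0.28), and camera adjusted p = 0.0386, with adjusted p = 0.674 with an estimated correlation. Each of these 4 calls was lost when a single library was left out. Without HuBL replicate 3 camera's adjusted p was 0.115, 0.204, 0.212 and 0.339 for the B cell, plasma cell, MHC class II and cell cycle lists; without BT3xHuBL replicate 2 it was 0.134, 0.164 and 0.23 for the last 3. Without BT3xHuBL replicate 3 it was 0.222, 0.129 and 0.233 for the B cell, MHC class II and cell cycle lists. The B cell call was also lost without HuBL replicate 4 (0.212) or BT3xHuBL replicate 4 (0.0615), the MHC class II call without BT3xHuBL replicate 4 (0.142), and the cell cycle call without HuBL replicate 2 (0.169).

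The lists of resident macrophages, cholesterol synthesis, bile acids and lipoproteins were not called in the liver with all libraries. The Kupffer cell list had a median of −0.03, the resident macrophage list 0.05 and the foamy macrophage list −0.06, with camera adjusted p = 0.99, 0.51 and 0.868 and with means of opposite sign in the Kupffer (0.03) and foamy (0.06) lists, and Cd68 gave −0.06 (SE 0.18), and −0.20 to 0.090 with 1 library left out. The Kupffer list was called higher without BT3xHuBL replicate 3 (0.0406) and the cholesterol synthesis list lower in the liver without BT3xHuBL replicate 1 (0.00759). The cholesterol synthesis, bile acid, and lipoprotein and clearance lists had medians of −0.00295, −0.06 and 0.02, with camera adjusted p = 0.868, 0.213 and 0.693; in the first and the last of them the test's direction was opposite to the median. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, measured 138 ± 117 and 117 ± 67.9 CPM in HuBL and BT3xHuBL, with a log2 fold change of −0.23 that became 0.56 without HuBL replicate 2 and −0.54 without BT3xHuBL replicate 2, and Akr1d1, another enzyme of that pathway, gave −0.58 (SE 0.14). Lrp1, a receptor for lipoprotein remnants, gave 0.41 (SE 0.13) and Apob 0.02 (SE 0.11), the latter −0.020 to 0.063 with 1 library left out. Acta2, a marker of activated stellate cells, gave −1.03 (SE 0.39), and −0.53 without HuBL replicate 3. The stellate cell and fibrosis list had 8 of 11 genes above 0 with a median of 0.21 (camera adjusted p = 0.135), and was called higher without BT3xHuBL replicate 2 (0.00097). The xenobiotic list, called higher in the aorta, had 10 of 14 genes below 0 with a median of −0.16 (camera adjusted p = 0.772). The circadian clock list, called in the aorta, had a median of 0.26 in the liver with camera adjusted p = 0.185. Over the 22 lists not called, camera's adjusted p ran from 0.0713 to 0.99.

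**Figure D3:**
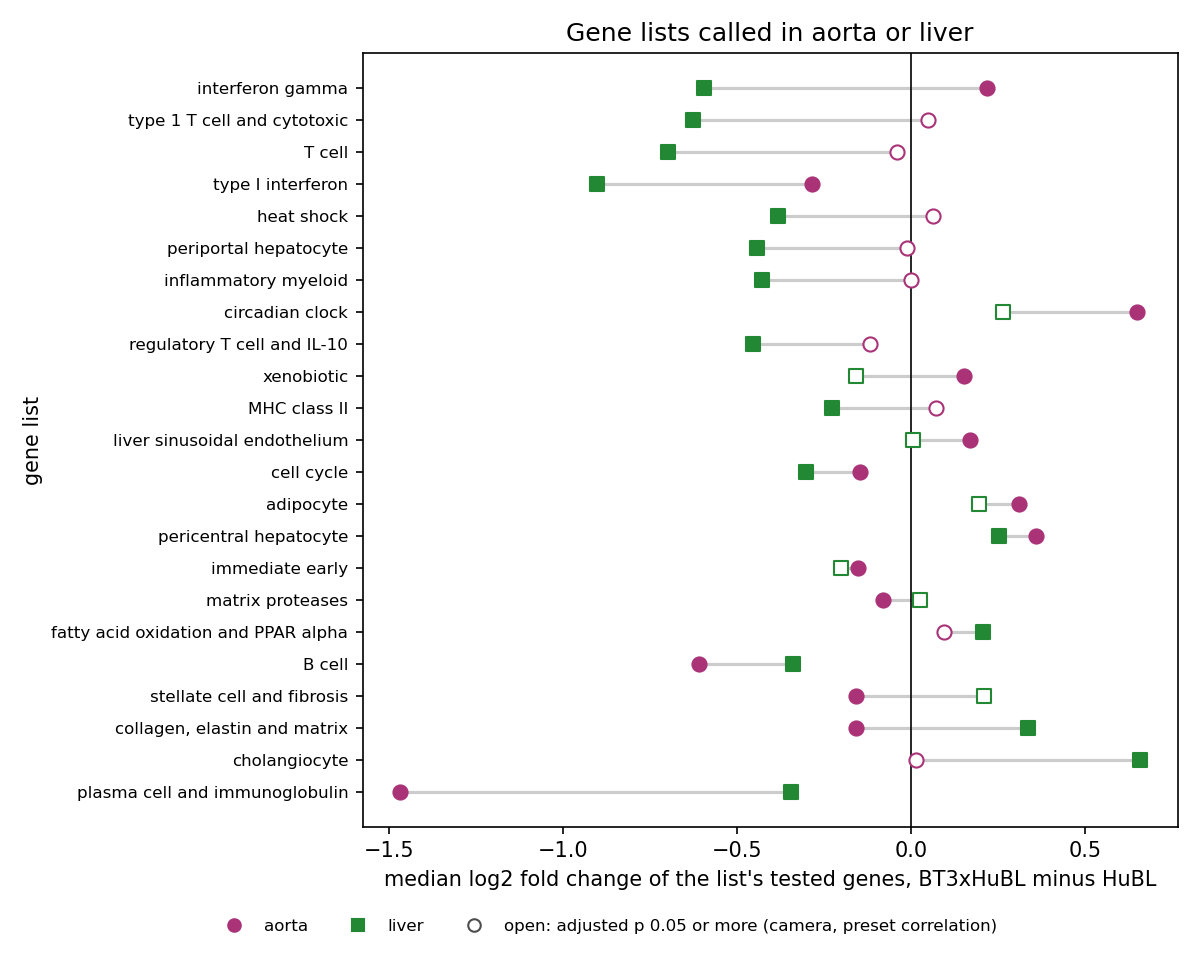
Median log2 fold change (BT3xHuBL minus HuBL) of each gene list tested in both tissues and called in at least 1 of them; circles are aorta and squares are liver, and filled symbols mark lists called by camera at the preset correlation. The interferon gamma list lay at 0.22 in the aorta and −0.60 in the liver, and the plasma cell and immunoglobulin list at −1.47 and −0.35; with an estimated correlation none of these calls held.

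Whether the genotype difference itself differed between tissues was tested as an interaction in one fit of the 14 libraries. The fit took the libraries as independent, and the labels do not say whether aorta and liver came from the same mice. Of 11951 genes, 0 passed in edgeR (smallest adjusted p = 0.21), 1029 had an unadjusted p under 0.05 where chance gives 598, and DESeq2 called 42 and limma-voom 0. Of 60 splits of the libraries, the real one included, 5 gave as many as 1029, and the highest other gave 1284. Without BT3xHuBL liver replicate 2 edgeR called 4. The genes of smallest p with a higher difference in the aorta than in the liver were Pycard, an inflammasome adaptor (1.25, SE 0.22), H2-D1 (0.81, SE 0.15), Gldc, which cleaves glycine (0.89, SE 0.17), Ube2h (0.63, SE 0.12), Slc25a51 (0.57, SE 0.11), Ptp4a1 (0.79, SE 0.16) and Rtp3 (0.84, SE 0.17). Those with a lower one were Bhlha15, a factor of secretory cells (−5.13, SE 0.98), and Steap2 (−1.88, SE 0.36). edgeR's adjusted p was 0.21 for each of these. No gene passed the test in both tissues.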

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

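The tests of shared reads, clock arms, Kupffer cells and the MHC region, the second scale for list scores, and the list tests of the interaction, were chosen only after the result was seen.

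Antibody and B cell lists lay lower in BT3xHuBL aortas, with calls lost in camera at adjusted p = 0.18 and 0.283 with an estimated correlation. Reads shared among near-identical antibody segments leave the single-copy genes unexplained. The 19 single-copy genes of the plasma cell and B cell lists had a median log2 fold change of −0.953, with 18 below 0. The SE of 0.149 is the spread across those genes, not across libraries. Both lists were known to lie low before this test, so the test adds nothing to these values. Lymph node or fat-associated lymphoid tissue carried into the HuBL dissections stays open: a list of 8 lymphoid stroma and naive lymphocyte genes differed by −0.286 (SE 0.115) and the B cell list by −0.686 (SE 0.285), a gap of 0.4 (SE 0.328) that is within 2 standard errors of 0 on a log2(CPM + 0.1) scale, and on the edgeR scale of the list scores −0.325 (SE 0.107), −0.756 (SE 0.326) and 0.432 (SE 0.355). Lef1, Ccr7 and Ltb, genes of lymphocytes, which the vessel wall also holds, had the lowest log2 fold changes of that list (−1.39, −0.655 and −0.421, SE 0.775, 0.313 and 0.21), while the other 5 lay between −0.0946 and 0.184 (Glycam1), with its most abundant genes, the B cell chemokine Cxcl13 and the chromatin organiser Satb1, at 8.95 and 5.61 CPM in HuBL and 8.48 and 5.81 CPM in BT3xHuBL. A difference in B lineage cells between the genotypes stays open, since no value here separates it from carried lymphoid tissue.

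Clock genes differed as a list in BT3xHuBL aortas, where Dbp passed and the list's call was lost in camera (adjusted p = 0.18 with an estimated correlation). The 9 genes that peak with Dbp were all above 0 (median 1.01) and the 3 that peak with Arntl all below 0 (median −1.08), a difference of 2.1 (SE 0.307). More of a single cell type in the samples was taken to move both arms the same way, which was not seen. That premise was not tested, and the directions were known before the test. The SE of that difference is the spread across clock genes, not across libraries. So a change in cell types is not excluded. A different time of day at collection is consistent with that difference, but the directions had been seen before the test, and collection times are not given in the sources used here. An effect of genotype on the clock stays open and untested.

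Interferon and T cell lists lay lower in BT3xHuBL livers, though no gene passed and the calls were lost in camera (adjusted p = 0.278 and 0.319 with an estimated correlation). Another MHC haplotype carried with the transgene, if it lowers only genes inside the MHC region, leaves the genes outside it unexplained. The 32 interferon list genes outside the region were all below 0 with a median of −0.732. The SE of 0.0741 is the spread across those genes, not across libraries. By library, the list scores differed by −0.682 (SE 0.208) for interferon gamma and −0.965 (SE 0.362) for type I interferon. All genes of both lists were known to be below 0, so this part of the test could not fail. Inside the region, 22 genes tested in both tissues were taken, those with symbols starting with H2-, Psmb, Tap or Ubd. Their medians were −0.393 in the liver and 0.0968 in the aorta. Other genes of the region were left out, so these medians do not cover the whole region. Fewer cells of every immune type cannot be told apart from fewer T cells, since the Kupffer cell score differed by −0.00553 (SE 0.273) and the T cell score by −0.695 (SE 0.254), a gap of 0.689 (SE 0.388) that is within 2 standard errors of 0 on that log2(CPM + 0.1) scale, and on the edgeR scale −0.00554 (SE 0.273), −0.677 (SE 0.248) and 0.672 (SE 0.384). A lower interferon response or fewer T cells with the BT3xHuBL genotype stays open and untested.

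Other splits of the libraries were fitted in the same way. In the aorta the 10 splits are too few for a share under 0.05. The real split gave 4 genes, and the highest of the others 2 genes (1 of 10 as large). For lists called, 6 of the 10 splits, the real one included, gave as many as the real 14. The others had a median of 14 lists and a highest of 17. For genes at an unadjusted p under 0.05, 6 of the 10 gave as many as the real 629, and the highest other gave 1287. In these last counts the real aorta split did not stand above the others. In the liver, for the number of genes at an unadjusted p under 0.05, 1 of the 35 splits, the real one, gave as many as 1381. The highest other gave 1213. That share is under 0.05, but it is the smallest that 35 splits can give and was not adjusted over the counts tested. The liver library names also run in genotype order, so this split cannot tell genotype from library order. Chance cannot be excluded for liver lists called (17, highest other 22, 6 of 35). The same holds for interaction lists called, where 60 splits were drawn (9, highest other 20, 37 of 60). It also holds for interaction genes at an unadjusted p under 0.05 (1029, highest other 1284, 5 of 60). For genes called in the liver and in the interaction the real count was 0, which every split reaches (35 of 35 and 60 of 60), so the splits say nothing about chance there; the highest others were 6 and 12.

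The list differences between tissues were tested with camera on the interaction at the preset correlation, which called 9 of 38 lists; with an estimated correlation it called 0 (4 at an unadjusted p under 0.05, smallest adjusted p = 0.455). The median difference, aorta minus liver, was 0.854 for interferon gamma, 0.441 for type I interferon, 0.707 for T cell, 0.789 for type 1 T cell and cytotoxic, 0.647 for inflammatory myeloid and 0.375 for heat shock genes. It was −0.625 for collagen, elastin and matrix, −1.02 for plasma cell and immunoglobulin and −0.45 for B cell genes. The clock list, at 0.0952, was not called (camera adjusted p = 0.866).

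In the liver, 15 of 210 groups of 4 values held a library far from the other 3 by Dixon's ratio, where chance marks about 1 in 20, or 10.5. In HuBL, Apela was at 11.3 CPM (others 4.82 to 4.86) and Ighg2b at 1.63 CPM (4.44 to 4.94) in replicate 4, Tmtc2 at 6.69 CPM in replicate 1 (5.80 to 5.94), and Cyp7a1 at 313 CPM in replicate 2 (64.7 to 93.4). HuBL replicate 3 had Acta2 at 9.48 CPM (3.16 to 3.99) and Il1a at 4.37 CPM (5.68 to 5.81). BT3xHuBL replicate 1 had H2-Ab1 at 40.0 CPM (20.5 to 22.0), Cd74 at 80.6 CPM (50.7 to 52.5), Epcam at 6.5 CPM (2.2 to 2.71) and a foamy macrophage list score of 4.88 (4.34 to 4.42). BT3xHuBL replicate 2 had Irf7 at 387 CPM (190.0 to 223). BT3xHuBL replicate 3 had Hspe1 at 32.6 CPM (21.7 to 22.8) and a heat shock list score of 5.29 (4.17 to 4.32). BT3xHuBL replicate 4 had Cyp4a14 at 1280.0 CPM (254 to 344) and an acute phase list score of 10.1 (8.26 to 8.49).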

How the results depend on the processing

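The clock covariate in the aorta, fry's mixed test and the list test of the interaction were chosen only after the result was seen; other alternatives were planned. The 4 aorta genes called became 75 with DESeq2, 9 with no filter, 7 in one fit of both tissues, 2 without receptor genes (fewer genes tested), and 0 with limma-voom, glmTreat, the adipocyte covariate or the clock covariate; leaving out each library gave 0 to 27. The liver count of 0 became 130 with DESeq2, 5 in one fit of both tissues and 52 with the clock covariate, and 0 to 5 with a library left out. The interaction count of 0 became 42 with DESeq2 and 0 to 4 with a library left out. Lists called (14 in the aorta, 17 in the liver) were 0 with an estimated correlation, 0 with fry, 5 and 10 with fry's mixed test, and 14 to 20 and 12 to 18 with a library left out; the 9 interaction lists became 0 with an estimated correlation. With the replicate number as a block, 14 aorta and 10 liver genes, 18 aorta lists and 16 liver lists and 0 interaction genes were called. Foamy macrophage was among these aorta lists (camera adjusted p = 0.0357). Between the genotypes, deviations of same-numbered libraries correlated at −0.06, 0.14 and 0.01 in the aorta and −0.04, 0.16, 0.10 and 0.07 in the liver. Not every library correlated best with its own number, so nothing here shows that the numbers pair the genotypes. Aorta and liver libraries of a genotype were not correlated with each other. The 4 called genes kept their direction in all alternatives run: Dbp 0.426 to 1.6 (edgeR, DESeq2 or limma adjusted p 4.81e-22 to 1.0, past the threshold in 12 of 20), Tcap 0.47 to 1.34 (7.88e-15 to 0.84, 13 of 20), Igkv10-96 −1.85 to −1.59 (6.17e-15 to 0.725, 12 of 19) and Igkv8-30 −5.32 to −2.66 (8.84e-13 to 0.423, 8 of 18). Of 834 values of 61 aorta genes under alternatives that kept all libraries, 752 kept direction and side of the threshold, 32 passed it, 19 no longer did and 31 reversed; of 833 for 66 liver genes these were 776, 56, 0 and 1, and of 45 for 9 interaction genes 40 kept both and 5 passed. The aorta reversals under the clock covariate, 90.1% of whose variance lies between genotypes so that little of the genotype difference can be told from it, were log2 fold changes of −0.36 for Chil3, −0.24 for Tef, 0.32 for Arntl, 0.22 for Btg2, 0.074 for Rasl11a, 0.39 for Cd79a, −1.39 for Trac, 0.26 for Lox, 1.20 for Eln, 0.44 for Egr1, 0.67 for Jun, −0.43 for Gbp4, −0.049 for Igtp, −0.0633 for aorta Apob, −0.33 for Adamts1, 0.67 for Adamts4, −0.049 for Glul, −0.61 for Cyp2e1, −0.18 for C1qa, 0.58 for Isg15, 1.13 for Foxp3, −1.39 for Cd4, −4.25 for aorta Trbc1, −2.82 for aorta Trbc2, 0.79 for Acta2, 0.72 for Col1a1 and 0.39 for Col3a1. The clock covariate was the mean log2 CPM of Dbp and Per2 minus that of Arntl. Its fit adjusted these genes partly for themselves, so the loss of Dbp and the reversal of Arntl under it were built in. The adipocyte covariate likewise holds Pnpla2, Pparg and Plin4. Other reversals were Foxp3 1.18 and Trbc2 −0.040 with the adipocyte covariate, aorta Cd4 −0.028 with limma-voom, Cd4 −0.046 with the replicate block, and in the liver Apob −0.025 with the clock covariate. With a library left out, 0 of the 4 called genes, 17 of 57 other aorta genes and 15 of 66 liver genes moved by over 1.5 times or changed sign. The aorta ranges that crossed 0 were Foxp3 −1.12 to 0.24, Cd4 −0.333 to 0.181, Trbc2 −0.0849 to 0.506, Acta2 −0.259 to 0.0173 and Cd68 −0.109 to 0.0415, and in the liver Trbc1 −0.395 to 0.0782, Apob −0.0199 to 0.0626, Cyp7a1 −0.54 to 0.56 and Cd68 −0.195 to 0.0904. Apart from the receptor genes and the clock covariate, the cause was not tested. Low counts limit Il10, at 8 to 69 counts per aorta library, and Foxp3. They also limit T cell genes in the liver, where Trbc1 and Trbc2 together held 30 to 62 counts per library. The liver T cell list summed to 33.1 CPM in HuBL and 19.5 CPM in BT3xHuBL.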

Other observations

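The tests of receptor segments were chosen only after the result was seen. The V-beta segment Trbv31, on chromosome 6 from 41557691 to 41558452 in GENCODE M21 (GRCm38), was singled out after its values were seen, since earlier BT lines were made from T cells using it. In the aorta it took 10 of 119 V-beta counts in HuBL replicate 1 (8.4%, exact 95% interval 4.1 to 14.9), 0 of 60 in replicate 2 (upper limit 5.96%) and 1 of 188 in replicate 3 (0.532%, interval 0.0135 to 2.93). In BT3xHuBL it took 32 of 82 in replicate 1 (39.0%, interval 28.4 to 50.4), 38 of 110 in replicate 2 (34.5%, interval 25.7 to 44.2) and 2 of 40 in replicate 3 (5.0%, interval 0.611 to 16.9). The mean share was 2.98% ± 4.7 in HuBL and 26.2% ± 18.5 in BT3xHuBL (SD, n = 3 each), with an exact two-sided permutation p of 0.2, where 0.1 is the smallest possible. Counts of the other V-beta segments were 119 ± 64.0 and 53.3 ± 17.2 (exact permutation p = 0.2). Liver libraries held 3 to 14 V-beta counts each, of which Trbv31 took 0 in every HuBL library and 2, 3, 0 and 1 in BT3xHuBL.

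On the first principal component of the aorta libraries (27.4% of variance), BT3xHuBL replicates 1, 2 and 3 were at 26.4, 39.7 and −19.9 and HuBL replicates 1, 2 and 3 at −27.5, 1.4 and −20.1. On the second (21.9%) the BT3xHuBL libraries were at 25.7, −8.8 and 32.8 and the HuBL libraries at −5.0, −33.0 and −11.7. BT3xHuBL replicate 3, with the lowest Trbv31 share of its group, was the BT3xHuBL library nearest to HuBL for Dbp (68.2 CPM). The same held for Tcap, Per2, Myocd, Actn2, Tent5b, Cys1, Chil3, Tef and Rasl10b, the other higher genes of smallest p. Among the lower ones it was nearest for Ms4a1, Arntl, Leo1, Btg2 and Rasl11a. It was farthest from HuBL for Igkv8-30 (0.244 CPM), Pou2af1 and Ly6c2. For Cemip and the other called kappa segment it lay between the other BT3xHuBL libraries. These comparisons were chosen after the values were seen. The Trbv31 share of BT3xHuBL replicate 3 lay within the HuBL range, so these values leave its genotype label in doubt. Without it edgeR called 27 aorta genes instead of 4.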
